A study of Mus musculus with 23 samples.

How the data were processed

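RNA was measured in blood stem and progenitor cells sorted from the bone marrow of wild-type (WT) mice and of SclCre;V617F mice, in which tamoxifen switches on the V617F form of the kinase JAK2. Per the labels, C57BL/6 mice received tamoxifen on 5 days and marrow was taken 12 weeks later. Long-term stem cells (LT-HSC; lineage-negative, Kit-positive, Sca-1-positive, CD48-negative, CD150-positive), the CD41-negative and CD41-positive fractions of the same gate, and megakaryocyte progenitors (MkP; lineage-negative, Kit-positive, Sca-1-negative, CD150-positive, CD41-positive) were sorted into lysis buffer, and RNA with an integrity number above 8 was kept. Libraries of LT-HSC and MkP were made with SMART-Seq v2 and those of the CD41 fractions with SMART-Seq v4, each followed by Nextera XT. Protocol and population could therefore not be separated, and no LT-HSC or MkP library was compared with a CD41-fraction library directly.

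The authors aligned reads to mm10 with STAR 2.5.2a and name R 3.4.2 and limma; the counting tool and annotation were not given in the sources used here. The deposited table holds whole-number counts per gene by Entrez identifier, with a column of gene lengths in bases per the file headers, for 24454 genes in 23 libraries with a median of 22.2 M counts. Of these identifiers, 24374 (99.7%) matched a gene with a chromosome in the reference annotation, and 11 had no symbol. Because the reference was not shown to be the authors' own annotation, chromosomes are given without positions.

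Counts of each protocol were analysed apart in R 4.3.3 with edgeR 4.0.16, with TMM scaling, the default filterByExpr filter on groups, a design of 1 mean per group and the quasi-likelihood F test, which left 14281 genes with SMART-Seq v2 and 14467 with v4. Of the 10 contrasts, 4 compared genotypes within a population, 4 compared populations within a genotype and the other two asked whether the genotype effect differed between populations. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. They measure the spread between libraries, estimated over all groups of a protocol together. Levels are CPM, counts per M of the TMM-scaled library total, given as mean ± SD over 3 libraries, or 2 for WT CD41-positive HSC. A fold against a group at 0 in all its libraries was taken against a floor of 3 counts per library and is written as at least that fold; the floor lay between 0.0597 and 0.171 CPM over the libraries. Intervals and floors of this kind cover counting error only.

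The contrasts, the tests of genes and lists, the gene lists, the rule for named genes and the alternatives, other than those named below as later, were chosen before the data were examined. Of 28 lists, 25 were tested with camera (limma 3.58.1) on log-CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, in contrasts where at least 5 members were measured. Adjusted p-values of lists are over the lists of a contrast. The remaining lists hold the mutated gene and Cre driver, the sort markers and the sex-linked genes, and were read gene by gene. A gene was named when it was among the 8 largest changes per direction (5 for differences of genotype effects) that passed with a mean of at least 10 CPM and groups that did not overlap, leaving out predicted, pseudo- and sex-linked genes. It was also named when it was among the 4 members of a described list with the smallest adjusted p, or in a fixed set read in every contrast, from which values are given where they bear on the comparison. Some genes chosen by these rules are not reported here. The CD41 and MkP signatures are the 200 genes with the largest passing change per direction in one protocol, tested in the libraries of the other.

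Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter, a filter of 5 CPM in 3 libraries and a fit of only the groups compared. Each library, the male mouse, and genes on X and Y were omitted in turn. Further alternatives were sex as a covariate in the CD41 fractions, the replicate number as a block, camera with an estimated correlation, signatures of 100 and 400 genes, and agreement at an unadjusted p of 0.01. Sample-weighted voom, omission of CD41-negative WT libraries 1 and 3, and all alternatives for calls shared between fractions or genotypes were chosen after seeing the data. Sex as a covariate could not be fitted for the LT-HSC contrasts, where sex and genotype coincide. No library was left out of the results reported.

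Whether equal replicate numbers mark the same mouse was checked from residual profiles. The V617F CD41-fraction libraries of equal number correlated at r = 0.301, 0.419 and 0.298 across genes, and the highest value between different numbers was -0.00601. Residuals of a group sum to 0, so positive values at equal numbers force the others down, and the latter are no separate evidence. The values show a link between V617F libraries of equal number, not that they came from 1 mouse. In WT, equal numbers gave r from -0.0328 to 0.0429, so WT numbers were not taken to pair libraries. Replicate libraries of a group differed by more than resampling of 1 library would give (lowest chi-square per degree of freedom 7.34).

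The pipeline was tested on simulated data built from these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Unchanged genes were given the same mean and the same spread in both groups compared. Genes missing from WT libraries alone, or a spread that differs between genotypes, were therefore not simulated. The false calls below do not cover them. With a 4-fold change, edgeR recovered 3% in the LT-HSC genotype contrast, 0% in MkP, 95% in CD41-negative HSC, 86% in CD41-positive HSC, 4% and 3% for MkP against LT-HSC in WT and V617F, and 82% and 85% for the CD41 fractions in WT and V617F. It made 0 to 11 false calls and 0 calls in the wrong direction. In MkP, where edgeR and limma-voom recovered 0% with 0 false calls, DESeq2 recovered 37% with 40 false calls. In CD41-negative HSC DESeq2 recovered 96% with 31 false calls and limma-voom 95% with 8, against 95% with 7 for edgeR.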

Results

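The series holds 23 RNA-seq libraries of sorted mouse marrow cells in 8 groups, WT and V617F cells of 4 populations. There were 3 libraries in each group except WT CD41-positive HSC, which had 2. Total counts per library ran from 17.6 to 49.2 M, with a median of 22.2 M, and in the CD41 fractions from 17.6 to 28.5 M. WT LT-HSC and MkP libraries held 30.9 M counts or more. Fewer genes had counts in them than in V617F, 13365 ± 466 genes in WT LT-HSC against 15547 ± 217 in V617F LT-HSC, and 11995 ± 491 in WT MkP against 14953 ± 281 in V617F MkP. Of the genes with a mean of 10 CPM or more, 2.53 ± 1.52% stood at 0 in a WT MkP library. The CD41 fractions were closer together, with group means between 15937 and 16414 genes.

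**Figure D1:**
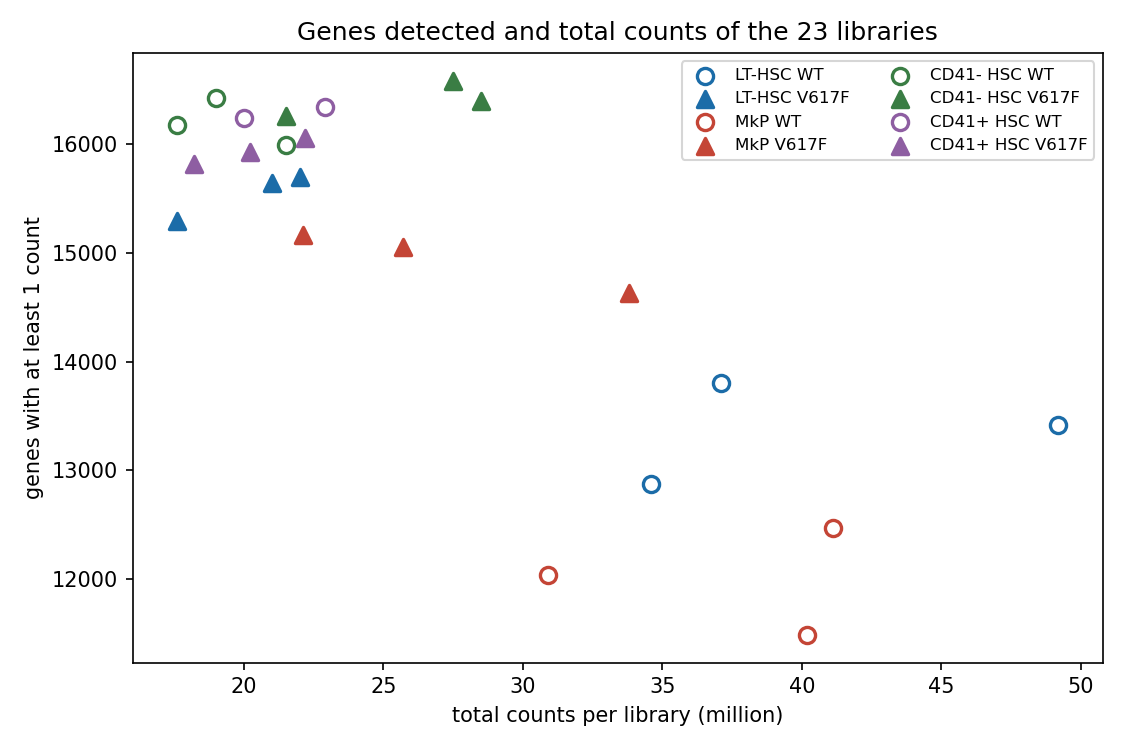
Each point is 1 library, with its total counts (M) on the x axis and its number of genes with at least 1 count on the y axis; open circles are WT and filled triangles V617F, coloured by population. WT MkP libraries hold 11483 to 12463 genes at 30.9 to 41.1 M counts, fewer than the 14634 to 15167 genes of V617F MkP at 22.1 to 33.8 M.

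What V617F changed in CD41-negative HSC, the fraction of the gate without the megakaryocyte marker, was asked first of the genes under JAK2 control. Socs2 (Entrez 216233, chromosome 10), a feedback inhibitor induced by STAT5, was 6.96-fold higher, at 189 ± 35.3 CPM against 27.1 ± 7.94 in WT (adjusted p = 3.21e-05). Its relative Cish rose from 89.2 ± 19.1 to 191 ± 49.4 CPM (adjusted p = 0.0201), and the survival kinase Pim2 from 67.9 ± 9.05 to 153 ± 6.92 CPM (adjusted p = 0.00339). Jak2 itself did not pass (236 ± 19.8 against 217 ± 28.2 CPM, adjusted p = 0.498). Plk2 (Entrez 20620, chromosome 13), a polo-like kinase under p53 control, fell from 43.6 ± 6.96 to 2.88 ± 0.576 CPM (adjusted p = 1.68e-05). The erythroid carbonic anhydrase Car1 (Entrez 12346, chromosome 3) fell from 66.5 ± 42.9 to 1.55 ± 0.53 CPM (adjusted p = 6.35e-04).

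In total 1941 of 14467 genes passed in CD41-negative HSC, 793 higher and 1148 lower, and 591 changed 2-fold or more. The largest rises were in Nov, a matricellular protein (log2 6.58), the glutamate transporter Slc17a8 (3.15), the tetraspanin Cd53 (3.11), the tight junction scaffold Tjp1 (2.82), Ncam2 (2.57), Plac8 (2.53) and the apolipoprotein Apob (1.94). Next to Car1 and Plk2, the largest falls were in the alpha-globin genes Hba-a1 and Hba-a2 (log2 -6.76 for Hba-a1), Mir6236 (-3.56), the protease Htra3 (-2.96), Gatad1 (-2.51) and the mRNA-binding protein Igf2bp2 (-2.48). The sort marker Cd48 was low in both genotypes but higher in V617F, at 8.19 ± 1.79 against 1.95 ± 0.535 CPM (adjusted p = 0.00735). Itga2b, which encodes CD41, was lower, at 115.3 ± 20 against 187 ± 42.6 CPM (adjusted p = 0.0314). Cell numbers cannot be read from these levels.

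Among the lists called in V617F CD41-negative HSC, those of megakaryocyte, erythroid and self-renewal genes pointed down and those of mitosis and cholesterol synthesis up. Of 32 megakaryocyte and platelet genes 10 were lower and 0 higher (list adjusted p = 5.46e-04). Zfpm1, a partner of GATA1, fell from 91.4 ± 47.2 to 25.4 ± 6.34 CPM and the clotting factor Vwf from 149.8 ± 39.6 to 81.9 ± 10.5 CPM. Of 26 erythroid genes 15 were lower and 0 higher (3.86e-07), Car1, Ermap, Rhd and Cited4 with the smallest p. Of 32 self-renewal and quiescence genes 9 were lower and 1 higher (8.50e-04), including the cell cycle inhibitor Cdkn1c at 30.3 ± 3.58 against 78.3 ± 15.8 CPM and Ndn at 41.8 ± 5.33 against 104 ± 19.3 CPM. Mitosis genes moved the other way: 11 of 30 were higher and 0 lower, 18 when adjusted over the list alone (1.52e-07). The kinesin Cenpe stood at 42.7 ± 8.05 against 23.4 ± 7.3 CPM and Nusap1 at 79.4 ± 9.66 against 46.5 ± 14.2 CPM. Cholesterol synthesis followed with 9 of 22 higher and 0 lower (3.72e-05), led by Hmgcs1, the synthase before the rate-limiting step, at 108 ± 9.21 against 51.4 ± 5.08 CPM (adjusted p = 0.00144). None of these 5 lists passed with an estimated correlation (adjusted p = 0.511 to 0.652).

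Smaller shifts in the same cells were DNA replication with 4 of 32 higher (list adjusted p = 0.0279) and oxidative phosphorylation with 1 of 38 higher (0.0146). The immediate early list, which also marks handling stress, had 7 of 24 lower, among them Junb and Egr1 (0.00206). Of 15 monocyte and macrophage markers 2 were higher and 6 lower, with C1qa, C1qb and C1qc below 3 CPM in either genotype (0.0149). JAK-STAT feedback and target genes went both ways, 5 of 19 higher and 3 lower, with Gadd45g and Bcl6 among the lower, and the list was not called (0.986). Interferon genes were not called either (0.136), with 4 of 39 lower. Among the 3 WT libraries, Lars2 took 1.38% and 1.68% of counts in numbers 1 and 3 and 0.101% in number 4. Number 1 held the granulocyte transcripts Mpo at 75.7 CPM and Ngp at 112 CPM, with 4.16 or fewer CPM of Mpo in the other WT libraries. None of the 4 smaller calls passed with an estimated correlation (adjusted p = 0.652 to 0.798).

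The count in CD41-negative HSC depended on each library: it was 620, 348 and 6021 without WT 1, 3 and 4, and 303, 403 and 282 without V617F 1, 2 (the male mouse) and 3, and 145 without WT 1 and 3 together, which leaves 1 WT library with a spread assumed from the other groups. It was 366 without both libraries of the male mouse, 269 when only these 6 libraries were fitted, 3380 with DESeq2 and 3964 with sample weights. The list calls for DNA replication (up to adjusted p = 0.216, without WT 3, WT 4 or V617F 3) and oxidative phosphorylation (up to 0.360, without WT 3 or V617F 1) each ended with an omission.

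CD41-positive HSC, the fraction of the gate that carries the megakaryocyte marker, were compared next to see whether V617F acted there as well. Socs2 was again higher, at 96 ± 13.6 against 23.1 ± 1.83 CPM (log2 2.06, adjusted p = 0.0015), and Plk2 again lower, at 1.16 ± 0.53 against 26.1 ± 2.32 CPM (log2 -4.47, adjusted p = 1.76e-05). Slc17a8 rose 10.2-fold to 43.1 ± 2.33 CPM, and Plac8, Tjp1, the sialomucin Podxl (135 ± 33.4 against 28.4 ± 0.717 CPM) and the cytokine receptor chain Csf2rb (30.7 ± 4.11 against 8.8 ± 3.18 CPM) rose too. The chemokine Cxcl12, which retains stem cells in their niche, fell from 24.1 ± 12.1 to 1.12 ± 0.527 CPM (adjusted p = 0.0061), and the interferon-inducible GTPases Gbp4, Gbp6, Gbp9 and Gbp10, all on chromosome 5, fell together (log2 -2.42 to -2.12). Altogether 168 of 14467 genes passed, 32 higher and 136 lower, 143 of them by 2-fold or more. Beyond these, Rgs7bp (3.54-fold) and Mmp2 (3.04-fold) were higher and Sult1a1 (5.79-fold) and Tinagl1 (4.55-fold) lower.

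Interferon response genes had the smallest list adjusted p at the preset correlation in V617F CD41-positive HSC, with DNA replication next. Over single omissions the adjusted p-values of these lists overlapped. Of 39 members 3 were lower (Ifit1, Mx2 and Ifi44), or 19 when adjusted over the list alone, and 0 were higher (7.82e-14). Stem cell genes fell, 3 of 32 lower (Mllt3, Ndn and Egr1; 3.34e-06). Genes that mark aged HSC fell too, 4 of 23 lower and 1 higher (1.24e-05): Runx1t1 and Fhl1 fell and the scramblase family member Plscr2 rose from 31.6 ± 0.0634 to 91.5 ± 13.4 CPM. Erythroid genes had 5 of 26 lower, Car1 among them at 0.977 ± 0.625 against 23.4 ± 5.49 CPM (2.12e-04), and immediate early genes had 3 of 24 lower (1.04e-05). Of the megakaryocyte list 0 of 32 passed, though the list was called lower (0.00108). These lists had adjusted p = 0.216 to 0.334 with an estimated correlation.

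Growth lists in V617F CD41-positive HSC were shifted upwards as whole lists without single genes passing. All 30 mitosis genes (2.53e-08), all 32 DNA replication genes (6.10e-13) and all 38 oxidative phosphorylation genes (8.50e-07) had positive fold changes, with median log2 values of 0.31, 0.36 and 0.23. Cholesterol synthesis (20 of 22 positive, 1.65e-04) and ribosome biogenesis (22 of 26 positive, 0.0136) had 0 passing members as well. Endothelial and stromal markers were lower, with Cxcl12 and Lepr passing of 10 (0.00159). Lymphoid priming genes had 1 of 10 lower, Ltb (0.018), NF-kB genes 0 of 23 (0.00402) and monocyte markers 1 of 15, Vcam1 (0.0227). With an estimated correlation these lists had adjusted p = 0.216 to 0.491.

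With 2 WT libraries the count for CD41-positive HSC was 32 and 53 without WT 3 and 4, 54 and 72 without V617F 1 and 3, 455 with DESeq2, 1854 with sample weights, 262 without a filter and 520 with only the groups compared. Calls that ended with an omission were the megakaryocyte (without V617F 2, adjusted p = 0.335), lymphoid (V617F 3, 0.0530), ribosome (WT 3 or V617F 3, up to 0.264), NF-kB (WT 3, 0.159) and monocyte lists (WT 4, V617F 2 or 3, up to 0.157).

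Both CD41 fractions shared a genotype response. Of 1862 genes outside X and Y that passed in CD41-negative HSC and were tested in both, 87.2% had the same sign in CD41-positive HSC, against 67.7% of all genes. Among them 28 were higher and 99 lower in both fractions, where independent lists would share 1.68 and 10.9, and 0 passed in opposite directions. Slc17a8, Tjp1, Plac8, Socs2, Plk2 and Car1 belong to this set. V617F libraries of equal number correlated between the fractions, so the lists are not independent. The shared count ran from 31 without CD41-positive WT 3 to 131 without CD41-negative WT 4, with 46, 49, 64, 77 and 79 without CD41-positive WT 4, V617F 1 and 3 and CD41-negative V617F 1 and 3.

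**Figure D2:**
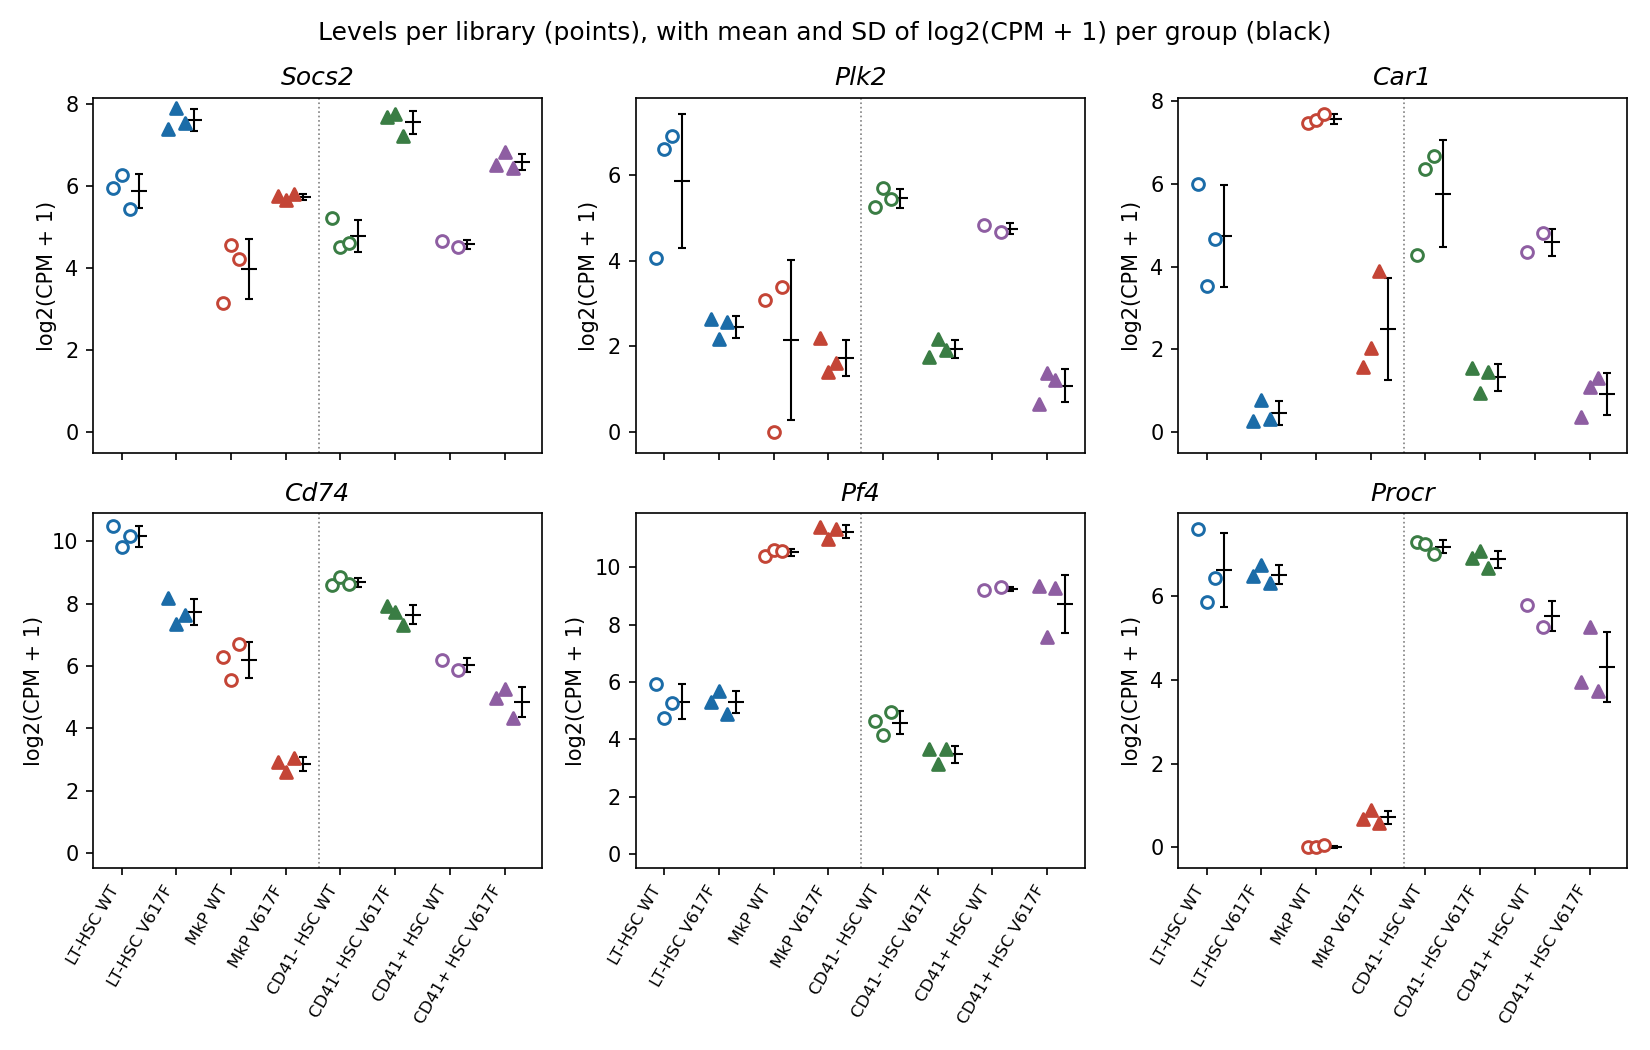
Points are single libraries on a scale of log2(CPM + 1), circles WT and triangles V617F, with the group mean and SD in black; a dotted line parts the protocols. Socs2 averages 189 and 96 CPM in V617F CD41-negative and CD41-positive HSC against 27.1 and 23.1 CPM in WT, while Plk2 averages 2.88 and 1.16 CPM against 43.6 and 26.1 CPM.

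LT-HSC, sorted with the same gate but without the CD41 split, answered the same question in the other protocol, with V617F labelled male and WT labelled female, so genotype and sex coincided. The small GTPase Rac1 (272 ± 22.2 against 23.1 ± 14.4 CPM, log2 3.56) and the lysosomal membrane protein Lamp1 (307 ± 40.7 against 23 ± 9.42 CPM, log2 3.74) were higher in V617F. The zinc finger protein Zfand5 (172 ± 62.7 against 13.4 ± 6.99 CPM, log2 3.68) was higher as well, and Ltbp1, a binding protein of latent TGF-beta, was at least 21.3-fold higher at 1.9 ± 0.749 CPM. Cyclin D1 (Ccnd1, 16.4 ± 1.32 against 95.4 ± 24.9 CPM), the MHC class II invariant chain Cd74 (218 ± 65.2 against 1170 ± 270 CPM) and Car1 (0.395 ± 0.289 against 32.6 ± 27 CPM) were lower. So were Pdlim7 (46 ± 9.02 against 222 ± 76.4 CPM) and Xist (3.21 ± 0.293 against 98.2 ± 33.8 CPM). These 9 of 14281 genes passed, with adjusted p between 0.0163 and 0.0376. Of them only Xist lies on X or Y, so no Y-linked gene passed between the groups labelled male and female. Socs2 stood at 197 ± 37.2 against 59.8 ± 16.8 CPM and Jak2 at 82.2 ± 21.5 against 24.8 ± 11.1 CPM without passing (adjusted p = 0.154 and 0.149).

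Of the lists in LT-HSC, markers of granulocyte progenitors and neutrophils, cells that the gate should exclude, were lower in all 18 members, with a median log2 of -2.93 (list adjusted p = 1.62e-21). Of these 0 passed over all genes and 13 passed when adjusted over the list alone, Mpo standing at 87.3 ± 73.8 against 909 ± 418 CPM and Ngp at 117 ± 78.9 against 1472 ± 999 CPM. Oxidative phosphorylation genes were lower in 36 of 38 members, median log2 -0.70, with 0 passing (2.26e-05); Uqcrc1, Cox6a1 and Cyc1 had the smallest p. Unfolded protein and stress response genes were lower, median log2 -0.68, with 0 of 20 passing (2.04e-04), Dnajc3 standing at 148 ± 23.7 against 376 ± 112 CPM. Endothelial and stromal markers were higher, median log2 1.46, 0 of 10 passing (0.00308), with Sparc and Alpl at 8.45 ± 8.66 and 2.1 ± 0.338 CPM in V617F. WT library 30 stood apart, with Spearman correlations of 0.754 and 0.756 to the other WT LT-HSC, which correlated with each other at 0.894, and a share of 8.55% of counts in its 10 most abundant genes. With an estimated correlation the granulocyte list had adjusted p = 0.0633, the stress response and endothelial lists 0.112 and oxidative phosphorylation 0.507.

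Leaving out any 1 of the 6 LT-HSC libraries moved the count: it was 0 without WT 32 or V617F 6, 7 or 8, 15 without WT 30 and 23 without WT 31. DESeq2, limma-voom and a fit of these libraries alone called 500, 316 and 0 genes. Without WT 30 the oxidative phosphorylation list turned upwards (adjusted p = 0.677), and without WT 31 the endothelial list was lost (0.0617).

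Between the protocols, Car1, Ccnd1, Cd74 and Pdlim7 were lower in both LT-HSC and CD41-negative HSC, where chance would share 0.318 genes, and Car1 and Cd74 were lower in CD41-positive HSC as well. Of the 8 LT-HSC calls outside X and Y, 87.5% had the same sign in CD41-negative and 62.5% in CD41-positive HSC, against 53.1% and 49.3% of all genes. Of the higher calls 0 passed in either fraction, where their median log2 was 0.10 and -0.01. At an unadjusted p of 0.01 the shares were 57.6% and 50.9%.

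MkP, the progenitors committed to platelets, were compared to see what V617F changed one step further. Car1 was lower (6.28 ± 6.53 against 189 ± 15.9 CPM, adjusted p = 0.0198), and so was Cd74 (6.27 ± 1.12 against 75.7 ± 28.7 CPM, adjusted p = 0.00339). The blood group protein Ermap and the sphingosine kinase Sphk1 fell from 36.2 ± 11.4 to 0.825 ± 0.641 CPM and from 53.7 ± 30.2 to 0.501 ± 0.692 CPM. Rac1 was higher here too (342 ± 32.4 against 29 ± 7.06 CPM, log2 3.56, adjusted p = 0.00339). So were the stress kinase gene Mapk8 (29.4 ± 2.67 against 1.46 ± 1.54 CPM), the TGF-beta antagonist Skil (40.9 ± 8.75 against 4.55 ± 2.42 CPM) and Tjp1, at 20.8 ± 5.61 CPM at least 251-fold above WT. Rac1 did not pass in either CD41 fraction, like the other higher calls of LT-HSC. In both LT-HSC and MkP the WT libraries held fewer genes than V617F, so its repeat is not independent of the protocol's WT libraries. Also named by rule were Prickle1, Ccser2, Pfkfb2 and Aak1 among the higher (log2 4.13 to 6.22) and Trib2, Atp1b2, P2ry2 and Pld4 among the lower (log2 -5.17 to -3.48). The platelet chemokine Pf4 (Entrez 56744, chromosome 5) stood at 2437 ± 352 against 1468 ± 119 CPM, Socs2 at 52.3 ± 2.99 against 16 ± 7.48 CPM and Jak2 at 115 ± 13.1 against 41.9 ± 5.47 CPM. None of these passed (adjusted p = 0.335, 0.0545 and 0.0757).

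Of 14281 genes 250 passed in MkP, 232 higher (92.8%) and 18 lower, and 171 of the higher genes were at 0 in all WT MkP libraries. Several of the higher genes belong to other programmes at levels of a few CPM or less, such as the stem cell genes Fgd5 (at least 25.3-fold) and Procr (0.651 ± 0.179 against 0.0109 ± 0.0189 CPM). Others are the JAK-STAT targets Socs3 (at least 31.4-fold) and Id1 (at least 22.8-fold), and the interferon gene Ifit3 (at least 16.4-fold). The stem cell, JAK-STAT and interferon lists themselves were not called in MkP. By mean level, 205 were higher and 0 lower under 5 CPM, 6 and 2 at 5 to 10 CPM, 10 and 11 at 10 to 50 CPM, and 11 and 5 at 50 CPM or more.

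All 10 list calls in MkP pointed down in V617F. Mitosis genes were lower in 27 of 30 members, median log2 -0.27, and DNA replication genes in 24 of 32, median log2 -0.33, with 0 passing in either (list adjusted p = 1.47e-04 and 1.43e-04). Aurka stood at 126 ± 6.88 against 223 ± 46.2 CPM and Cdc6 at 94.3 ± 4.92 against 187 ± 64.2 CPM. Both calls held with an estimated correlation (adjusted p = 0.0169 for each), as did those for B lineage (0 of 10 passing, 0.00111; 0.0442) and mast and basophil markers (0 of 8, 0.00139; 0.0442). Erythroid genes had 2 of 25 lower, Car1 and Ermap (1.43e-04; adjusted p = 0.0889 with an estimated correlation). Granulocyte markers had 1 of 18 lower, Mpo at 1062 ± 572 against 8103 ± 2090 CPM, or 13 lower and 1 higher when adjusted over the list alone (2.53e-11; adjusted p = 0.0706 with an estimated correlation). Monocyte markers, with Cd14 higher at least 7.84-fold and 0 of 15 lower, had a median log2 of -1.71 (0.00177; adjusted p = 0.102 with an estimated correlation). Lymphoid priming (1 of 11 lower, Dntt, 0.0305; adjusted p = 0.0889 with an estimated correlation; mean log2 0.06 but median -0.55) was also lower, as were ribosome biogenesis (0 of 26, 0.0374; adjusted p = 0.0889 with an estimated correlation) and glycolysis (0 of 20, 0.0199; adjusted p = 0.132 with an estimated correlation). The megakaryocyte list was not called (0 of 32 passing, 0.784).

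For MkP, the count was 415 without WT 30, 52, 46 and 91 without V617F 1, 2 and 3, and 1137, 878, 588 and 762 with DESeq2, limma-voom, sample weights and the groups alone. List calls lost with an omission were lymphoid (WT 31 or V617F 1, up to adjusted p = 0.208), ribosome (WT 30, WT 32 or V617F 2, up to 0.160) and glycolysis (WT 30 or 31, up to 0.105). Those for monocyte (WT 30, 0.139) and mast (WT 31 or V617F 1, up to 0.0865) markers were lost too.

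Genes that passed in MkP mostly had the opposite sign in the CD41 fractions. Outside X and Y, 38.7% and 35.8% of 243 MkP calls had the same sign in CD41-negative and CD41-positive HSC, against 53.4% and 51.2% of all genes. Passing in both MkP and CD41-positive HSC were Id1, Skil, Slc17a8 and Tjp1 (higher) and Car1, Cd74, Sphk1, Trib2 and Ermap (lower), where chance would share 0.520 and 0.169, and 9 genes passed in opposite directions. With CD41-negative HSC, 12 higher and 7 lower genes were shared (12.3 and 1.43 by chance) and 21 were opposite. How many opposite calls chance would give was not computed. Of all 250 MkP calls, 171 were higher genes at 0 in every WT MkP library. The opposite signs were therefore not shown to be a reversed response to V617F.

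CD41-positive and CD41-negative HSC were compared to learn how the marker divides the stem cell gate. Megakaryocyte genes were among those higher in CD41-positive cells in both genotypes, and stem cell genes among those lower. In WT, Pf4 was 26-fold higher (609 ± 29.1 against 23.4 ± 6.48 CPM), the platelet receptor subunit Gp1bb 16.8-fold higher (95.5 ± 3.6 against 5.68 ± 2.73 CPM) and Itga2b itself 4.57-fold higher (855 ± 86.1 against 187 ± 42.6 CPM). In V617F, Pf4 stood at 483 ± 256 against 10.3 ± 2.19 CPM, Gp1bb at 94.7 ± 31 against 3.48 ± 1.11 CPM and Itga2b at 697 ± 74.5 against 115.3 ± 20 CPM. The stem cell factors Hlf (187 ± 20.6 against 568 ± 133 CPM in WT, 132 ± 43.1 against 456 ± 25.9 CPM in V617F) and Gfi1 were lower. Gfi1 stood at 1.92 ± 1.5 against 26.2 ± 8.22 CPM and 1.25 ± 0.717 against 31.1 ± 11 CPM, and Ly6a, which encodes Sca-1, was lower too (log2 -1.66 and -2.08).

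In WT 4917 genes passed between the CD41 fractions, 2277 higher and 2640 lower, and in V617F 4960 passed, 2376 higher and 2584 lower. In both genotypes 1547 were higher and 1658 lower, where independent lists would share 374 and 472, and 2 passed in opposite directions. The WT gene count was 1949 and 1215 without CD41-positive WT 3 and 4, 1926 without CD41-negative WT 1 and 3 together, which leaves 1 such library, and 2028 with the groups alone, and the V617F count was 7952 with sample weights. Outside X and Y both genotypes shared 3110 calls, 1702 and 1104 without CD41-positive WT 3 and 4, 1723 without CD41-negative WT 1 and 3 together and 1829 with the groups alone. Other large rises were Pde10a, F2rl2, Serpine2, Cxcl12, Pls1 and Lhfp in WT and Pde10a, Ache, Tuba8, Cavin2, Alox5 and Mfsd2b in V617F. Large falls were Itgam, Ctss, Nhsl1, Fam117a and Satb1 in WT and Cd53, Ctss, Nov, Hk3, Sgsm1, Trib3 and Phldb2 in V617F. The granulocyte genes Ltf and Mpo also fell in WT, where their CD41-negative means of 18.9 ± 26.5 and 27.6 ± 41.6 CPM rest on library 1. Within V617F, the JAK-STAT targets Socs2 (96 ± 13.6 against 189 ± 35.3 CPM), Cish (90 ± 30 against 191 ± 49.4 CPM) and Pim1 (37.8 ± 4.77 against 80.4 ± 16.9 CPM) were lower in the CD41-positive cells. In WT Pim1 was (log2 -0.54), while Socs2 and Cish did not pass (adjusted p = 0.435 and 0.125).

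Every one of 30 mitosis genes was higher in CD41-positive cells in both genotypes, among them Birc5, Aurkb and Cdk1 (list adjusted p = 2.21e-27 and 7.02e-26). The proliferation marker Mki67 stood at 321 ± 24.2 against 91.1 ± 7 CPM in WT and 411 ± 57.8 against 119 ± 20.3 CPM in V617F. DNA replication had 29 and 32 of 32 higher (4.76e-16 and 7.81e-21), oxidative phosphorylation 32 and 30 of 38 (7.65e-11 and 1.16e-12) and megakaryocyte genes 23 and 24 of 32 (8.48e-10 and 8.37e-13). Also higher were ribosome biogenesis 11 and 13 of 26 (0.00845 and 3.37e-05) and aged HSC genes 11 and 10 of 23, with 1 and 2 lower (1.08e-04 and 0.00715), Clu, Cavin2, Itgb3 and Vwf leading in each genotype. Stem cell genes had 15 of 32 lower in each, with 2 and 3 higher (0.00215 and 0.00266). Lymphoid genes had 7 of 10 lower and 1 higher in each, Ltb, Flt3 and Lsp1 among the lower (0.00417 and 4.91e-04). Interferon genes had 10 and 24 of 39 lower and 1 higher, Irf1 and Ddx58 among the lower (0.0124 and 5.91e-07). In WT the further calls were glycolysis (9 of 20 lower and 1 higher, 0.0354), NF-kB (9 of 23 lower and 2 higher, 0.0435), granulocyte (7 of 14 lower, 0.0435) and monocyte markers (4 of 15 lower, 0.00315). The granulocyte genes Mpo and Ltf rested on CD41-negative WT 1, and list calls between the fractions were not tested without any library. No list call between the fractions held with an estimated correlation: the 13 in WT had adjusted p = 0.275 to 0.602 and the 9 in V617F adjusted p = 0.214 to 0.431.

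MkP against LT-HSC showed how far commitment to platelets takes the transcriptome. In WT, Pf4 was 35.6-fold higher in MkP (1468 ± 119 against 41.2 ± 17.7 CPM). So were the thrombin receptor F2rl2 (461 ± 174 against 12.9 ± 2.27 CPM), the urea transporter Slc14a1 (1339.7 ± 179 against 87.1 ± 24.4 CPM) and Vwf (358 ± 84.4 against 51.4 ± 17.5 CPM). The stem cell receptor Procr (Entrez 19124, chromosome 2) stood at 0.0109 ± 0.0189 CPM in MkP, below the level of 3 counts, against 111 ± 71 CPM in LT-HSC. Fgd5 was at least 418-fold and Sult1a1 at least 2264-fold lower. The gate markers followed the sort, with Ly6a at 1.29 ± 1.02 against 258 ± 237 CPM and Itga2b at 1620.3 ± 191 against 132 ± 96.1 CPM. In V617F, Pf4 stood at 2437 ± 352 against 39.2 ± 10.9 CPM, F2rl2 at 499 ± 88.7 against 12.7 ± 3.68 CPM and Procr at 0.651 ± 0.179 against 90.6 ± 14.1 CPM. Socs2 was lower in MkP in both genotypes (log2 -1.90 and -1.91).

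In WT 1271 of 14281 genes passed, 331 higher and 940 lower in MkP, and 466 of the lower genes were at 0 in every WT MkP library. In V617F 156 passed, 54 higher and 102 lower. Both genotypes shared 45 higher and 87 lower genes, where independent lists would share 1.25 and 6.71, and 0 were opposite. Outside X and Y 131 were shared, but 47, 38 and 48 without V617F LT-HSC 6, 7 and 8 and 28, 37 and 41 without V617F MkP 1, 2 and 3. The shared count was 544, 203, 553 and 14 with DESeq2, limma-voom, sample weights and the groups alone, and 5 with the replicate block. The potassium channel gene Kcnj5 led in both (156 ± 58.9 and 95.8 ± 25.8 CPM, with LT-HSC below the level of 3 counts); Ltbp1, Ifi209, Grap2, Prss34, Pde10a, Gp1bb and Slc35d3 in WT and Pde10a, Plek, Rgs10, Serpine2 and P2ry1 in V617F also rose most. Falling most were Hid1, Efna1, Tmem37, Plxna4os1, Pde1b and Gsta4 in WT, each at least 447-fold, and Efna1, Gbp8, Myof, Sult1a1, Tinagl1 and Gsta4 in V617F.

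Megakaryocyte genes had 16 of 32 higher and 3 lower in WT MkP (list adjusted p = 8.52e-15) and 13 higher in V617F (2.50e-27). Mitosis had 17 of 30 higher in WT, Ccnb1 and Bub1b among them (7.26e-19), and 2 in V617F with all 30 positive (6.06e-21). DNA replication had 7 and 0 of 32 (1.85e-09 and 7.39e-10) and ribosome biogenesis 3 and 0 of 26 (1.73e-04 and 3.21e-07). Mast and basophil markers had 5 and 0 of 8 (2.79e-07 and 2.62e-07), with Prss34 at 70.4 ± 56.5 against 0.00944 ± 0.0163 CPM in WT. These 5 lists held in both genotypes with an estimated correlation. Stem cell genes had 8 and 5 of 32 lower and 1 higher in each (7.64e-05 and 3.51e-06; adjusted p = 0.0604 and 0.0253 with an estimated correlation). Interferon genes had 4 and 0 of 39 lower (1.43e-04 and 6.85e-06; adjusted p = 0.0709 and 0.0322 with an estimated correlation). NF-kB genes had 3 of 21 lower and 1 higher in WT and 0 passing in V617F (0.0255 and 0.0372; adjusted p = 0.0709 and 0.0699 with an estimated correlation). In WT the JAK-STAT list fell with 5 of 19 lower, Id1, Socs3, Socs2 and Pim2 among them (0.00431; adjusted p = 0.0915 with an estimated correlation). Erythroid genes rose with 5 of 25 higher and 2 lower (0.0192; adjusted p = 0.301 with an estimated correlation). In V617F the unfolded protein response (2 of 20 higher, Asns and Hsp90b1, 9.19e-06; 0.0253) and aged HSC genes (2 of 22 higher, Cavin2 and Vwf, and 1 lower, 0.00882; 0.0342) were called and held with an estimated correlation. So were lymphoid genes (2 of 11 lower, 1.85e-04; 0.0132) and endothelial markers (0 of 10, lower, 0.00611; 0.0455). Oxidative phosphorylation was called upwards (0 of 38 passing, 2.23e-05; adjusted p = 0.460 with an estimated correlation).

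In WT the MkP count stayed within 1001 and 1818 when any library was omitted, but was 2803 with DESeq2, 669 with sample weights and 14 with the groups alone. The omissions kept a spread per gene that WT and V617F groups share. WT replicates correlated less (Spearman 0.821 to 0.876 in MkP, 0.754 to 0.894 in LT-HSC) than V617F ones (0.968 to 0.991 and 0.929 to 0.969). The omissions therefore do not show that the WT count holds with the spread of WT libraries alone. In V617F, where LT-HSC were labelled male and MkP female (Xist 3.21 ± 0.293 CPM in LT-HSC and 574 ± 435 CPM in MkP), each omission moved the count. It was 52, 41 and 50 without LT-HSC 6, 7 and 8 and 31, 40 and 45 without MkP 1, 2 and 3, against 693, 306, 5320 and 2972 with DESeq2, limma-voom, sample weights and the groups alone.

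**Figure D3:**
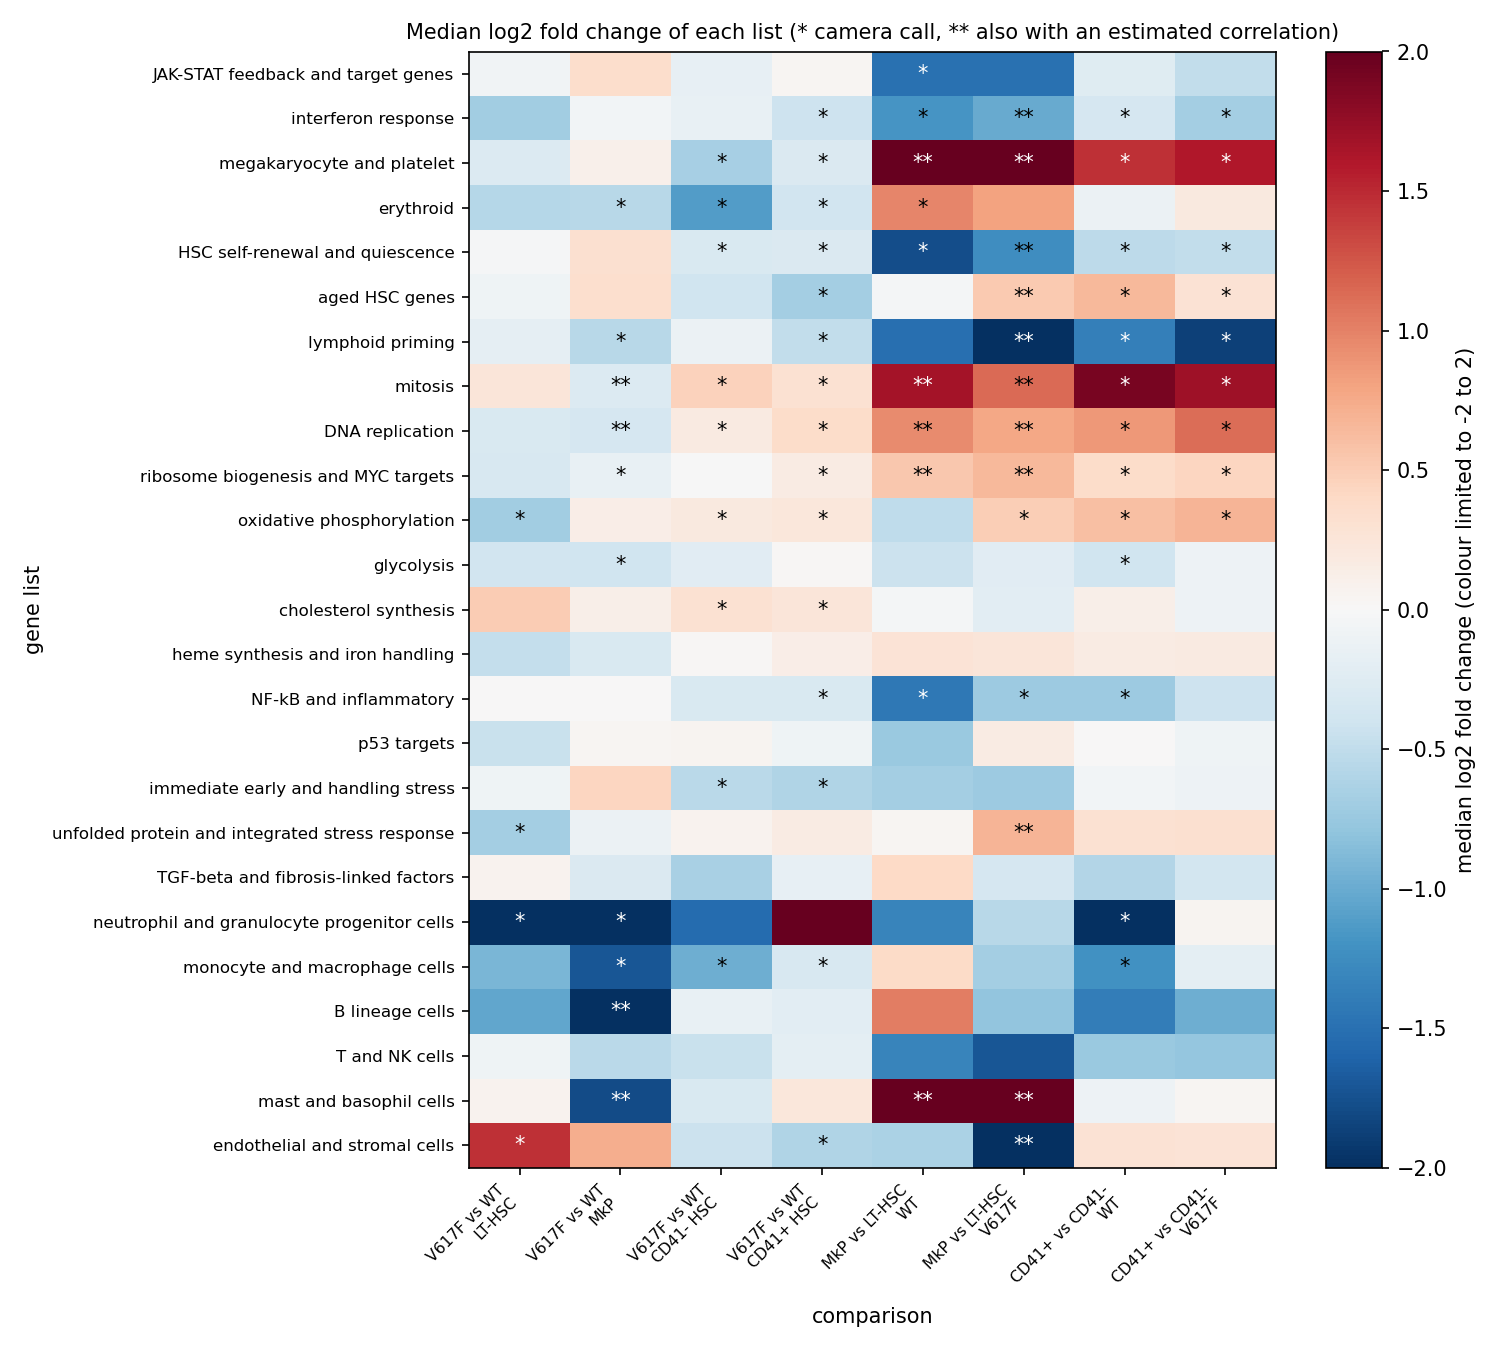
Colour shows the median log2 fold change of each of 25 gene lists (y axis) in the 8 comparisons (x axis), with genes at 0 in a group set to their bound and colour limited to -2 and 2; stars mark calls. Mitosis medians are 1.91 and 1.69 for CD41-positive against CD41-negative HSC in WT and V617F, and the granulocyte list is at -2.93 and -2.25 in V617F LT-HSC and MkP against WT.

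Whether V617F stem cells carried more of the MkP programme was asked with signatures taken from one protocol and read in the other. The 190 measured genes of the MkP-higher signature were not called for genotype in CD41-negative HSC (21 higher, 15 lower, adjusted p = 0.347; median log2 0.02, mean -0.08) or in CD41-positive HSC (2 higher, 1 lower, adjusted p = 0.0853). Genes lower in MkP than in LT-HSC fell with V617F in CD41-negative HSC (31 of 199 lower and 5 higher, adjusted p = 8.95e-05; adjusted p = 0.362 with an estimated correlation). They fell in CD41-positive HSC too (17 lower, 1 higher, adjusted p = 1.07e-19; adjusted p = 0.0575 with an estimated correlation). Between the CD41 fractions the MkP-higher signature rose in WT (113 higher, 5 lower, adjusted p = 8.34e-23) and in V617F (119 higher, 4 lower, adjusted p = 4.37e-24). The lower one fell (108 and 125 lower, 1 and 3 higher, adjusted p = 1.15e-15 and 3.96e-22). With an estimated correlation these had adjusted p = 0.0575 to 0.0740. The result for genotype hung on the size of the MkP-higher signature. With the 331 genes available for a size of 400 it was called higher in V617F in both fractions (adjusted p = 0.00391 and 2.24e-05), and with 100 genes its direction turned to lower without a call (0.346 and 0.389). In the other direction, the CD41-higher signature of 192 genes was higher in MkP than in LT-HSC in WT (55 higher, 0 lower, adjusted p = 1.89e-27) and in V617F (25 higher, 0 lower, adjusted p = 3.56e-54). The CD41-lower signature of 168 genes was lower (49 and 16 lower, 2 and 0 higher, adjusted p = 4.07e-14 and 3.60e-54). All 4 calls held with an estimated correlation. For genotype the CD41-higher signature was not called in LT-HSC or MkP (adjusted p = 0.0825 and 0.244). The CD41-lower signature was called higher in V617F LT-HSC (adjusted p = 0.00282; 0.0225 with an estimated correlation) with a median log2 of -0.16 and a mean of 0.79, and was not called in MkP (adjusted p = 0.379).

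Of the lists not yet named, heme synthesis and iron handling, p53 targets, TGF-beta and fibrosis-linked factors and T and NK markers passed in none of the 10 contrasts, with lowest adjusted p of 0.0577, 0.0791, 0.136 and 0.435. Differences of the genotype effect between populations were tested directly. Between MkP and LT-HSC 65 genes passed, 61 of them more positive in MkP, and 52 of the 65 were at 0 in all WT MkP libraries. For the CD41 fractions edgeR called 0 of 14467, with 1274 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. The 65 became 0 without LT-HSC V617F 6, 7 or 8, 15, 8 and 22 without MkP V617F 1, 2 and 3, 187 and 118 without LT-HSC WT 30 and 31, and 219, 117 and 141 without MkP WT 30, 31 and 32. The 0 between the CD41 fractions became 1766 without CD41-negative WT 4. Groups of 3 that did not overlap occurred for 2759 and 4433 of 14281 genes between genotypes in LT-HSC and MkP, 30.3% in CD41-negative HSC. They occurred for 20.6% and 41.5% between MkP and LT-HSC in WT and V617F, and for 56.1% between the CD41 fractions in V617F, against 10% by chance.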

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

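The tests of other splits, of the library that stands apart, of depth and capture in MkP, of a shared genotype effect, of mixed cells and wrong sex labels, and of carry-over read from all genes below the brought level were chosen only after the results were seen. Those of gene length and of carry-over read from genes under 25% of that level were written before.

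The genotype effect differed between MkP and LT-HSC for 65 genes in a direct test, 61 of them more positive in MkP. Of the 65 genes, 52 were at 0 in all WT MkP libraries, so their fitted differences depend on the prior count and are no measure of size. The largest fitted log2 differences were 11.94 for Gnat2 (10.3 ± 2.61 CPM in V617F MkP), 11.30 for Krtcap3 (4.48 ± 1.76 CPM), 11.15 for P4htm (6.03 ± 2.13 CPM), 11.11 for Mageh1 on chromosome X (6.52 ± 1.94 CPM) and 10.97 for Lmbr1l (5.35 ± 2.53 CPM), each at 0 in WT MkP and present in both LT-HSC groups. Ltbp1 went the other way (-9.34), at 24.1 ± 6.90 CPM in V617F and 33.1 ± 12.7 CPM in WT MkP against 1.90 ± 0.749 CPM in V617F LT-HSC and 0 in WT LT-HSC. With that 0, its fitted difference depends on the prior count as well and is no measure of size. All V617F LT-HSC were labelled male and the other groups female, so by the labels the difference carries sex as well. WT MkP libraries also held fewer genes than those of V617F MkP. Fewer transcripts captured in WT MkP was not tested for these genes and stays open. Among 100 splits of the libraries, 2 gave 65 genes or more, the real one included, and the highest other gave 86. The count was 0 without V617F LT-HSC 6, 7 or 8, 15, 8 and 22 without V617F MkP 1, 2 and 3, 187 and 118 without WT LT-HSC 30 and 31, and 219, 117 and 141 without WT MkP 30, 31 and 32.

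For the same difference between MkP and LT-HSC, 8 lists were called without a passing member. Mitosis was lower in the MkP effect (21 of 30 members negative, median log2 -0.57, adjusted p = 0.00155), as were DNA replication (median log2 -0.00, mean -0.13, 0.0477), cholesterol synthesis (14 of 22 negative, 0.0363), B lineage markers (8 of 10 negative, 0.0271) and mast and basophil markers (6 of 8 negative, 0.00715). Endothelial and stromal markers were called lower with 5 of 10 negative and a median of 0.14 (0.0363). Oxidative phosphorylation (31 of 38 positive, median log2 0.96, 0.0271) and granulocyte markers (15 of 18 positive, median log2 1.10, 0.00896) were higher. The LT-HSC side of the oxidative phosphorylation difference rested on WT 30 (median log2 -0.70 with it and 0.23 without). The list difference was not tested without that library. With an estimated correlation mitosis kept its call (adjusted p = 0.0469) and the others had adjusted p = 0.092 to 0.724. Of the 100 splits, 11 called 8 lists or more, with 15 at most, so chance is not excluded for the list count.

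Between the CD41 fractions 0 genes passed for a difference of genotype effects in edgeR (1274 at an unadjusted p under 0.05, 6 in DESeq2, 0 in limma-voom), with 1766 when CD41-negative WT 4 was left out. Without a passing member, 4 lists differed: interferon response was lower in the CD41-positive effect (33 of 39 negative, median log2 -0.36, adjusted p = 6.89e-05), and erythroid (20 of 26 positive, 5.69e-04), DNA replication (25 of 32 positive, 0.00970) and glycolysis genes (16 of 20 positive, 0.0254) were higher. Each had adjusted p = 0.987 with an estimated correlation.

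Oxidative phosphorylation genes were lower in V617F LT-HSC (median log2 -0.70) and higher in V617F CD41-positive HSC (0.23). Their median length of 969.5 bases is short, and a trend with gene length was tested with 10000 random lists of matched length. The lists fell at percentiles 1.27 and 99.22, outside the middle 95% of random lists (-0.67 to -0.07 and 0.01 to 0.20). Random lists had medians of -0.39 and 0.12, so genes of matched length shifted the same way. They ignore the correlation between genes of 1 pathway, which makes the range too narrow to decide whether length is the whole cause. The LT-HSC percentile was read with WT 30 included. In CD41-negative HSC, where the list was called higher too (median log2 0.20, adjusted p = 0.0146), it lay inside the range of random lists (-0.16 to 0.24, percentile 93.53), so length stays open there as well. That call was lost without WT 3 or V617F 1 (up to adjusted p = 0.360). With an estimated correlation none of these calls held: adjusted p = 0.507 in LT-HSC, 0.798 in CD41-negative and 0.388 in CD41-positive HSC. In LT-HSC the shift rested on WT 30: without it the median was 0.23 (22 of 38 members above 0, adjusted p = 0.677), and without each other library -1.11 to -0.62. That library may therefore be the source of the lower list in LT-HSC. All WT LT-HSC were labelled female and all V617F LT-HSC male, so sex and genotype coincide with or without WT 30. The median of 0.23 without it holds both together, in few libraries, and cannot argue against either of them alone. For CD41-positive HSC no other explanation was tested.

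In V617F MkP, 92.8% of 250 passing genes were higher. Shallower WT libraries are argued against, as WT MkP held 1.37 times the counts of V617F MkP (37.4 against 27.2 M), and so is a genotype effect shared with the CD41 fractions, where the median log2 change of these genes was -0.13 in CD41-negative (38.5% above 0) and -0.18 in CD41-positive HSC (32.9% above 0). In LT-HSC, the other population of the same protocol, the median of these genes was 0.30 (58.2% of 232 above 0, 3 passing higher), and WT libraries there also held fewer genes than V617F. Fewer transcripts captured in the WT libraries stays open: all 205 passing genes under 5 CPM were higher, against 6 of 8 at 5 to 10 CPM, 10 of 21 at 10 to 50 CPM and 68.75% of the 16 at 50 CPM or more. Capture and genotype coincide in these 6 libraries, so an effect of V617F stays open too, whether in MkP alone or shared with LT-HSC.

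The 5 WT libraries of the CD41 fractions, labelled female, held Y-linked transcripts at 20.27% to 30.5% of the level in the male V617F library of the fraction and Xist at 36.77% to 59.3% of the female V617F level. A male mouse labelled female is argued against by that Xist, since the male libraries held 2.36 CPM or less. Male and female cells mixed in a library may explain both values. Carry-over from the male V617F library of the fraction, as the whole source, would bring every transcript of that library at the Y-linked share. Of the genes at 10 CPM or more there, only 1, Nov, lay under 25% of the level brought at the mean share (0.222 against 8.83 CPM in CD41-negative WT), and 0 in the CD41-positive fraction. This was fewer than the 10 genes set beforehand to count against carry-over, so that test did not count against it. Taken at the smallest share of the 4 Y-linked genes per library, 5 genes lay below the brought level in every CD41-negative WT library (Socs2, Cd53, Tjp1, Slc17a8 and Nov) and 3 in every CD41-positive one (Podxl, Tjp1 and Slc17a8), with 99.9% counting bounds that did not meet. Slc17a8, for example, stood at 4.25 and 4.35 CPM in CD41-positive WT against 12.1 and 8.85 CPM brought. Only this test, chosen later, argues against such carry-over, and its bounds cover counting error alone. No biological explanation was tested.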

How the results depend on the processing

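Sample-weighted voom, omission of CD41-negative WT 1 and 3, and all alternatives for the shared calls were chosen only after the results were seen. Counts below are passing genes, with the value reported in the text in brackets at its first mention. Unless an alternative tests fewer libraries, the cause of a change was not tested.

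DESeq2 called 500 genes for genotype in LT-HSC (9), 1137 in MkP (250), 3380 in CD41-negative HSC (1941) and 455 in CD41-positive HSC (168). It called 2803 and 693 for MkP against LT-HSC in WT (1271) and V617F (156), 523 for the difference of genotype effects between MkP and LT-HSC (65), 6 for that between the CD41 fractions (0), 291 genotype calls shared by the fractions (127) and 544 MkP against LT-HSC calls shared by both genotypes outside X and Y (131). Limma-voom called 316 genes in LT-HSC, 878 in MkP and 306 for MkP against LT-HSC in V617F, with 203 shared by both genotypes. With sample weights the counts were 588 in MkP, 3964 in CD41-negative and 1854 in CD41-positive HSC, 669 and 5320 for MkP against LT-HSC in WT and V617F, 7952 for the CD41 fractions in V617F (4960), 0 and 496 for the differences of genotype effects between MkP and LT-HSC and between the fractions, 727 shared genotype calls and 553 MkP against LT-HSC calls shared by both genotypes.

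Fitting only the groups compared, and so fewer libraries, gave 0 genes in LT-HSC, 762 in MkP, 269 in CD41-negative and 520 in CD41-positive HSC, 14 and 2972 for MkP against LT-HSC in WT and V617F with 14 shared, 2028 for the CD41 fractions in WT (4917) and 1829 calls shared by both genotypes outside X and Y (3110). Without a filter 262 genes passed in CD41-positive HSC. Without the male mouse 366 passed in CD41-negative HSC. Without CD41-negative WT 1 and 3 the counts were 145 in CD41-negative HSC, 1926 for the CD41 fractions in WT, 56 shared genotype calls and 1723 shared fraction calls. With the replicate block, 3983 genes passed in CD41-negative HSC and 6 for MkP against LT-HSC in WT, of which 5 were shared with V617F. In these the numbers were not shown to pair libraries. The block gave 5771 for the CD41 fractions in V617F, where libraries of equal number correlated. RLE size factors, the filter of 5 CPM in 3 libraries, sex as a covariate and omission of X and Y genes left each of these counts within 1.5 times its reported value, and RLE moved the median of all genes by at most 0.0611 on the log2 scale. The covariate took sex from the labels. WT libraries of the CD41 fractions were labelled female but held Y-linked transcripts, so it cannot show whether the counts there depend on sex.

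Leaving out 1 library at a time gave 0 to 23 genes in LT-HSC, 46 to 415 in MkP, 282 to 6021 in CD41-negative HSC, 32 to 170 in CD41-positive HSC, 1001 (without WT MkP 31) to 1818 (without WT LT-HSC 32) and 31 to 52 for MkP against LT-HSC in WT and V617F, and 1215 to 7082 (without CD41-negative WT 4) and 3380 to 4721 (without CD41-positive V617F 3 and 2) for the CD41 fractions in WT and V617F. The differences of genotype effects ran from 0 to 219 and from 0 to 1766, the shared genotype calls from 31 to 131, the MkP against LT-HSC calls shared by both genotypes from 28 (without V617F MkP 1) to 138 (without WT LT-HSC 30) and the shared fraction calls from 1104 (without CD41-positive WT 4) to 3220 (without CD41-negative WT 4). Where an omission left 1 WT CD41-positive library, or that of WT 1 and 3 together left 1 WT CD41-negative library, that library was assumed to vary like the other groups. The list calls numbered 4 to 6 in LT-HSC, 7 to 13 in MkP, 8 to 13 in CD41-negative and 12 to 15 in CD41-positive HSC.

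With an estimated correlation the lists called for genotype were 0 in LT-HSC (4), 4 in MkP (10), 0 in CD41-negative HSC (9) and 0 in CD41-positive HSC (15). They were 5 for MkP against LT-HSC in WT (10), 0 and 0 for the CD41 fractions in WT (13) and V617F (9), and 1 and 0 for the differences of genotype effects (8 and 4). A larger correlation lowers camera's power by construction. Where list members correlate more than the preset value, however, the preset p-values are too small, and the lost calls cannot tell these readings apart. Other splits of the same libraries, with 0 genes passing, called up to 14 lists in CD41-negative HSC and 11 in MkP. They called up to 13 for the CD41 fractions in V617F, but at most 8 for MkP against LT-HSC in WT. Such splits mix the groups compared, so they do not decide it either. With an estimated correlation the adjusted p for the MkP-higher signature between the fractions was 0.0575 in WT and 0.0575 in V617F. For the MkP-lower signature it was 0.362 and 0.0575 for genotype in CD41-negative and CD41-positive HSC, and 0.0740 and 0.0575 for the fractions in WT and V617F. With 100 genes the MkP-higher signature turned to lower in V617F CD41-negative (adjusted p = 0.346) and CD41-positive HSC (0.389), and with 400, of which 331 were available, it was called higher in both (0.00391 and 2.24e-05).

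Of 265 gene values named in the text, 133 kept their side of the threshold under each alternative run for them. Over 3895 values under alternatives, 3330 stayed on their side, 519 lost it, 34 gained it and 12 turned direction. Those that turned were log2 changes of genes named for their level: Lars2 in CD41-negative HSC by genotype without CD41-negative WT 1 and 3 (0.18), Mpo there with limma-voom (1.27), sample weights (0.08), the replicate block (1.34), sex as a covariate (0.38), without V617F 2 or the male mouse (0.04 and 0.04) or WT 1 and 3 (2.99) and, over single omissions, from -0.72 to 2.74, Socs2 between the fractions in WT with the replicate block (0.03) and, over single omissions, from -0.37 to 0.05, and Jak2 by genotype in CD41-positive HSC over single omissions (-0.01 to 0.22). Apart from Lars2, none of these had passed.

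Depth limits low genes: 3 counts correspond to 0.0597 to 0.171 CPM per library, and genes at 0 in all libraries of 1 group have folds given as bounds.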

Other observations

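All the splits of libraries below were tested only after the results were seen.

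Socs2 and Plk2 set the genotypes apart in both CD41 fractions, in opposite directions, and their V617F and WT libraries did not overlap in either. Between the fractions, Socs2, Cish and Pim1 were lower in V617F CD41-positive than in V617F CD41-negative HSC, while in WT only Pim1 of these passed. The genotype effect on Socs2 was not shown to differ between the fractions (adjusted p = 0.566 for the difference).

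Jak2 stood at 24.8 ± 11.1 and 41.9 ± 5.47 CPM in WT LT-HSC and MkP and at 82.2 ± 21.5 and 115 ± 13.1 CPM in V617F, where the protocol was SMART-Seq v2. In the CD41 fractions, made with v4, it stood at 217 ± 28.2 and 179 ± 19.8 CPM in WT and 236 ± 19.8 and 192 ± 17.9 CPM in V617F. The Cre driver's gene Tal1 did not pass for genotype in CD41-negative HSC (adjusted p = 0.841) or LT-HSC (0.947).

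For the comparisons of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave the most genes each time (so 1 of the 10 was as large): 9 in LT-HSC, 250 in MkP and 1941 in CD41-negative HSC for genotype, with 0 at most in the other splits, 1271 for MkP against LT-HSC in WT with 19 at most, 156 in V617F with 0, and 4960 for the CD41 fractions in V617F with 0. In the last, where libraries of equal number correlated, the 3 other splits that part 3 such pairs and the 6 that part 1 pair each called 0 genes. Each of these splits mixes both fractions within a group, and genes that differ between the fractions then widen the spread. The 0 calls therefore cannot show whether the link between equal numbers matters. The other splits of the remaining comparisons mix their groups in the same way.

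Lists were called in other splits as well. As many lists as in the real split were called in 5 of 10 splits in LT-HSC (4, highest other 5), 2 in MkP (10, highest other 11), 4 in CD41-negative HSC (9, highest other 14), 1 and 3 for MkP against LT-HSC in WT (10, highest other 8) and V617F (13, highest other 14), and 6 for the CD41 fractions in V617F (9, highest other 13). For the signature lists the numbers were 3 of 10 in LT-HSC (1, highest other 1), 10 in MkP (0, highest other 0), 7 in CD41-negative HSC (1, highest other 2), and 10 in each of MkP against LT-HSC in WT, in V617F and the CD41 fractions in V617F (2, highest other 2).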
